A study of Homo sapiens with 4 samples.

How the data were processed

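CUT&RUN for EZH2 was performed in HEK293 cells with an induced H3.1-WT or H3.1-K27M histone, with an anti-rabbit HRP secondary antibody as negative control. There were 4 libraries, 1 per combination of genotype and antibody, and the antibody was taken from the sample titles. The titles of the libraries called H3.1-K27M here, and the peak list made from them, read H31, which does not name the mutation. Their genotype was taken from the genotype label of the same samples, which gives H3.1-K27M. The submitters' processing notes name cutadapt, Bowtie2 2.3.5.1, Picard, MACS2 and deepTools, and the build hg19, without roles, order or parameters. The authors deposited 2 lists of broad peaks, 1 per genotype, each naming 1 EZH2 library against 1 HRP library, so peaks were called per sample and not on pooled samples.

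Each deposited peak carries a fold enrichment, a linear ratio of EZH2 signal over the background estimated by the authors' caller. The HRP library was the control, and how the caller set the background is not given in the sources used here. It also carries a −log10 p and a −log10 q value, which the authors' caller gave and which are deposited as such. The lowest −log10 q was 1.01 in the H3.1-WT list and 1.00 in the H3.1-K27M list, which corresponds to a q of about 0.1. The scaling between EZH2 and HRP libraries is not given in the sources used here. Since the caller compares read numbers, the number and strength of peaks depend on the depth of both libraries, and depth is unknown because the lists hold no read counts. Fold enrichments and q values were used to describe, rank or filter peaks. Numbers of peaks past the same minimum were set side by side between the lists, and 1 alternative used a fold minimum pooled over both lists. Because these values depend on depth and scaling, such counts describe the lists and do not measure a change in bound EZH2.

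The build was checked against chromosome lengths: 0 peaks ended past an hg19 chromosome end and 179 past an hg38 end. All peaks lay on the 24 assembled chromosomes, and no peaks overlapped within a list. Positions are 1-based in hg19. Covered length is the number of bases in merged peaks. Peaks were counted as overlapping when they shared at least 1 base. Chance overlap came from 100 seeded shifts of 1 list along each chromosome, either by any distance or by 100 kb to 1 Mb, and describes these lists without a p-value. Union regions were formed by merging both lists. Shares have 95% Wilson intervals, and the quotient of strong-peak ratios has a conditional exact 95% interval; both cover counting error only and treat peaks as independent. Overlap and merging were tested on simulated lists of 20000 sites with known shared shares. After correction for chance overlap the largest error was 0.0513 percentage points, with 0 disagreements with bedtools. The overlap shares reported here carry no such correction, so this error does not apply to them.

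Giemsa bands came from the band table of circlize 0.4.16, whose chromosome ends equal the hg19 lengths in GenomeInfoDb 1.38.1. A peak was assigned to the band of its midpoint. The bands of the HOX clusters were taken from general knowledge of their location. Analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, bedtools 2.31.1 and R 4.3.3.

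The comparisons of peak number, covered length, overlap, union regions and covered length per chromosome or band stain were fixed before the data were examined, as were the first set of alternatives (a −log10 q of at least 5, a fold enrichment at or above the pooled median of 3.36, the top 15538 peaks of each list, chromosomes 1 to 22 and X, a reciprocal overlap of 50%, and peaks within 5000 bases joined). The rule for named regions was fixed then too: the 5 widest peaks of each list, the 5 regions of each single genotype with the highest fold enrichment, the 5 windows of 1 Mb with the largest covered length per list, and the HOX clusters as a group. The other thresholds, the autosomes-only values, the X windows, the quotients of dark over light bands and the random band sets were chosen after seeing the data.

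No genome or gene annotation of hg19 was used here. Promoters with a peak, peak bases by annotation class and the 13 gene lists fixed beforehand were therefore not analysed here. The HRP libraries enter only through the authors' peak calls.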

Results

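EZH2 is the catalytic subunit of PRC2, the Polycomb complex that methylates lysine 27 of histone H3, and K27M replaces that lysine with methionine. Binding of EZH2 was mapped by CUT&RUN, in which an antibody directs a nuclease to its target in permeabilised cells and the released DNA is sequenced. The cells were HEK293, an established human embryonic kidney line, carrying a lentiviral, doxycycline-induced H3.1-WT or H3.1-K27M histone. The 4 libraries comprised 1 EZH2 library and 1 HRP library per genotype. The HRP library, made with the secondary antibody alone, was the background control. The deposited data were 1 list of EZH2 peaks per genotype, each called against the HRP library of the same genotype. With 1 library per group, no difference between the genotypes has a replicate check, and no test between them was made. The lists give no read counts, so the depth of each library is unknown. Fold enrichments and −log10 q values of single peaks are the authors' own.

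The first comparison asked how much of the genome carried EZH2 peaks in each genotype. The H3.1-K27M list was longer than the H3.1-WT list and had a larger share of peaks near the caller's limit. It held 35016 peaks against 31077, a ratio of 1.13, and covered 42.957 Mb against 35.381 Mb, a ratio of 1.21. Median peak width was 825 bases in H3.1-K27M and 778 bases in H3.1-WT. In H3.1-K27M 75.5% of peaks had a −log10 q under 2, against 58.1% in H3.1-WT.

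Strong peaks were fewer in the H3.1-K27M list. At a −log10 q of at least 5, called strong peaks here, H3.1-K27M had 654 peaks and H3.1-WT 2107, a ratio of 0.310. These covered 3.05 Mb and 6.94 Mb, with median widths of 3468 and 2629 bases. At a minimum of 10 the numbers were 143 and 735, and at 20 they were 18 and 229. The direction of the comparison therefore turned with the threshold: the ratio of peak numbers was already 0.658 at a minimum of 2. Strong peaks were fewer in H3.1-K27M on each of the 22 autosomes, with ratios from 0.157 on chromosome 22 to 0.395 on chromosome 9. A q value depends on depth, which is unknown, so these counts describe the lists rather than amounts of bound EZH2.

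**Figure D1:**
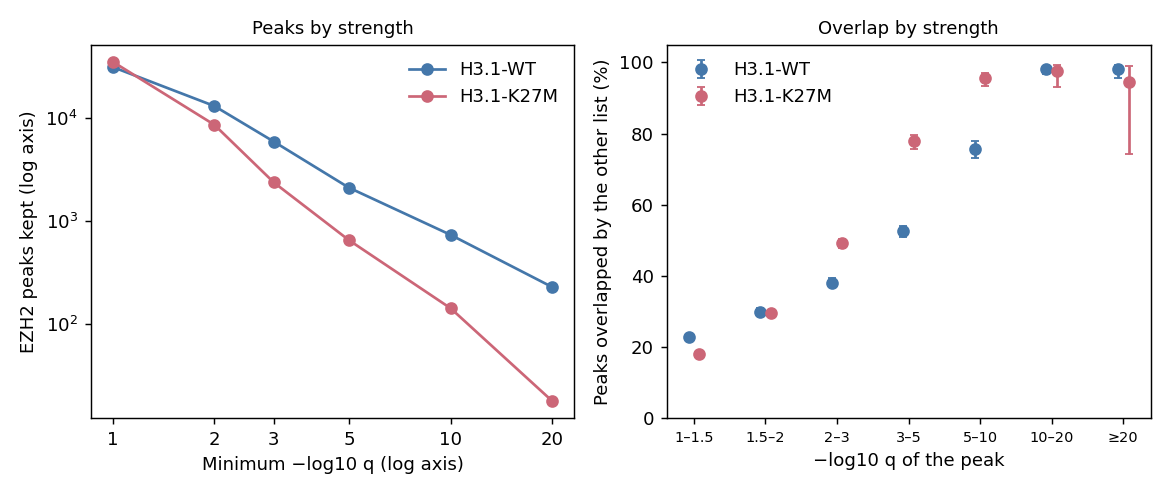
Left, number of EZH2 peaks kept at each minimum −log10 q (both axes logarithmic); right, percent of peaks of each list overlapped by the other list, by the peak's own −log10 q, with 95% Wilson intervals. H3.1-K27M has more peaks at a minimum of 1 (35016 against 31077) and fewer from a minimum of 2 on.

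The next comparison asked whether EZH2 occupied the same regions in both genotypes. The strongest sites of either genotype were nearly always present in the other list, and weak peaks mostly were not. Of the 735 H3.1-WT peaks with a −log10 q of at least 10, 722 were overlapped by an H3.1-K27M peak (98.2%, 95% Wilson interval 97.0% to 99.0%). Of the 143 such H3.1-K27M peaks, 139 were overlapped by an H3.1-WT peak (97.2%, 93.0% to 98.9%). Among the weakest peaks, with a −log10 q from 1 to 1.5, the shares were 22.8% of 9681 H3.1-WT peaks and 18.0% of 15384 H3.1-K27M peaks.

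Over all peaks, 36.0% of H3.1-WT peaks were overlapped by H3.1-K27M peaks (35.5% to 36.5%), against a mean of 3.21% when peaks were shifted along whole chromosomes and 4.61% when shifted within 1 Mb. For H3.1-K27M peaks the share was 31.6% (31.09% to 32.07%), against 2.85% and 4.09%. The lists shared 12.112 Mb of 66.225 Mb covered by either, a Jaccard index of 18.3% against 0.787% and 1.17% after shifting. Merging both lists gave 54546 regions. Of these 19.6% held peaks of both genotypes, 36.5% of H3.1-WT alone and 43.9% of H3.1-K27M alone. Regions with both had a median width of 1856 bases, against 626 bases for regions of H3.1-WT alone and 736 bases for regions of H3.1-K27M alone. Of the 2107 strong H3.1-WT peaks, 1759 were overlapped by an H3.1-K27M peak of any strength (83.5%, 81.8% to 85.0%), and of the 654 strong H3.1-K27M peaks 627 by an H3.1-WT peak (95.9%, 94.1% to 97.1%). When both lists were limited to strong peaks, 70.7% of regions held an H3.1-WT peak alone and 5.49% an H3.1-K27M peak alone, a split that follows in part from the unequal list lengths. The intervals cover counting error only.

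The widest peaks of each list were covered in large part by the other list. No filter for repeats or poorly mapped regions was applied here, so shared calls need not mean shared EZH2 binding. The widest H3.1-WT peak lay in band 18q21.1 (hg19, chromosome 18, 44764442 to 44791974; 27533 bases, fold enrichment 9.51), and 25958 of its bases were also covered in H3.1-K27M, where it was the third widest peak. The second widest, in 12q24.13 (chromosome 12, 113898240 to 113922407), was 24168 bases wide with a fold enrichment of 9.65, and 22660 of its bases were covered in H3.1-K27M. Beside the centromere of chromosome 2, peaks in 2p11.1 (91657476 to 91678453) and 2p11.2 (90437845 to 90458754) had fold enrichments of 12.2 and 15.8 in H3.1-WT, and 20756 and 17314 of their bases lay in the H3.1-K27M list. The fifth, in 19p13.3 (chromosome 19, 1746709 to 1765417), was 18709 bases wide with 17531 shared. The widest H3.1-K27M peak, in 1p36.32 (chromosome 1, 2589598 to 2631156), spanned 41559 bases, of which 24805 were covered in H3.1-WT. Those in 19p13.2 (chromosome 19, 8852007 to 8883454) and 6q12 (chromosome 6, 63542118 to 63568228) spanned 31448 and 26111 bases, with 23719 and 21743 covered in H3.1-WT.

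The regions of H3.1-WT alone with the highest fold enrichment lay in 15q13.2 (chromosome 15, 30483916 to 30484952, fold enrichment 8.20), 20q13.13 (chromosome 20, 47894697 to 47895073, 7.84), 19q13.11 (chromosome 19, 33793058 to 33794529, 7.76), 13q34 (chromosome 13, 113260468 to 113260762, 7.46) and 20q13.12 (chromosome 20, 43922128 to 43922544, 7.35). Their widths ran from 295 to 1472 bases, around the median of 626 bases for regions of H3.1-WT alone. In H3.1-K27M the corresponding regions lay in 2p11.2 (chromosome 2, 89180111 to 89180410, 7.96), 14q31.1 (chromosome 14, 83322396 to 83322659, 6.81), 11q14.2 (chromosome 11, 86454661 to 86454930, 6.69), 12q23.1 (chromosome 12, 98791162 to 98791422, 6.27) and 2q36.1 (chromosome 2, 223520843 to 223521143, 6.16). These were 261 to 301 bases wide, close to the shortest peak of that list, 255 bases. No gene annotation of hg19 was used here, so peaks are given by position and band without gene names.

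Chromosome X stood apart from the autosomes. It carried 6632 peaks in H3.1-K27M and 1985 in H3.1-WT, a ratio of 3.34, and 8.27 Mb against 2.16 Mb of covered length, a ratio of 3.83. X held 19.2% of the covered length in H3.1-K27M and 6.09% in H3.1-WT, and it makes up 5.02% of the genome. The ratio of peak numbers was 4.36 on Xq and 2.56 on Xp. Each of the 31 windows of 5 Mb with peaks had more in H3.1-K27M, from 1.03 times as many at 0 to 5 Mb to 10 times as many at 125 to 130 Mb, with a median of 3.30.

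The excess on X relative to autosomes held up to a −log10 q of 3 and was uncertain among strong peaks. At a minimum −log10 q of 2 there were 1290 peaks in H3.1-K27M and 650 in H3.1-WT, at 3 there were 235 and 233, and at 5 there were 30 and 71. The ratio on X divided by the autosomal ratio was 3.42 over all peaks, 3.38 at a minimum of 2, 2.67 at 3 and 1.38 at 5, the last with a 95% interval of 0.862 to 2.17. H3.1-WT peaks on X were overlapped by the other list in 54.2% of cases and H3.1-K27M peaks on X in 15.5%. On autosomes together, H3.1-K27M had 28323 peaks and H3.1-WT 29018, a ratio of 0.976, so the larger total in H3.1-K27M came from X. Autosomal covered length was 34.581 Mb and 33.106 Mb, a ratio of 1.04.

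**Figure D2:**
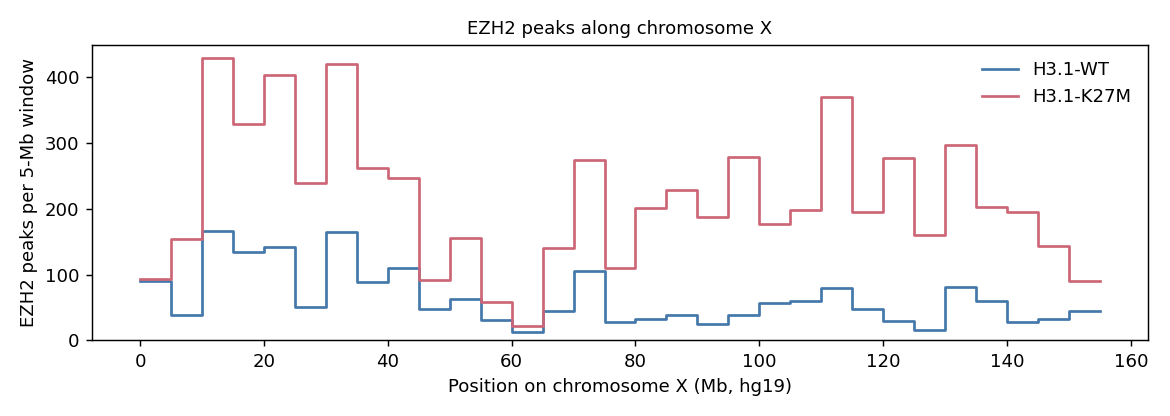
Number of EZH2 peaks in windows of 5 Mb along chromosome X (hg19) in H3.1-WT and H3.1-K27M. The H3.1-K27M line lies above the H3.1-WT line in each of the 31 windows.

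Among autosomes, the ratio of covered length ran from 0.610 on chromosome 15 to 1.38 on chromosome 5, with a median of 0.901. It was above 1 on 10 autosomes and below 1 on 12. Chromosome 6 was the most densely covered autosome in both genotypes, with 31.2 kb per Mb in H3.1-K27M and 25.3 kb per Mb in H3.1-WT. Chromosome 5 had 23.4 and 17.0 kb per Mb.

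**Figure D3:**
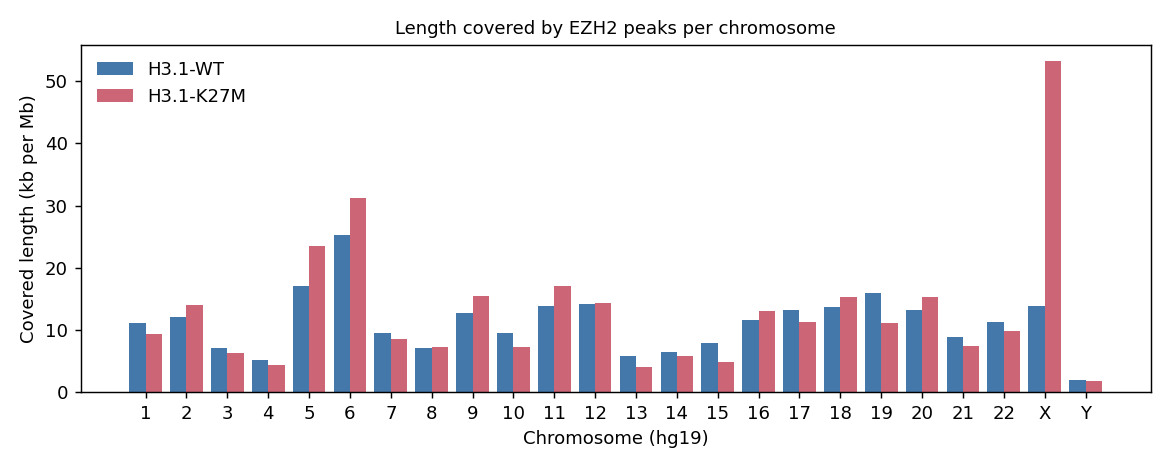
Length covered by EZH2 peaks per Mb of each chromosome (hg19) in H3.1-WT and H3.1-K27M. X reaches 53.2 kb per Mb in H3.1-K27M against 13.9 kb per Mb in H3.1-WT, and chromosome 6 is the highest autosome in both.

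The most densely covered windows of 1 Mb reached higher values in H3.1-K27M. They lay in 9p23 (chromosome 9, 9000001 to 10000000), with 253607 covered bases against 86077 in H3.1-WT, in 6p12.3 (chromosome 6, 50000001 to 51000000), with 248438 against 81092, and in 6q12 (chromosome 6, 65000001 to 66000000), with 239893 against 70422. The next were adjoining windows in Xp22.2, from 13000001 and from 14000001, with 238694 and 216215 covered bases against 82103 and 47132. The densest H3.1-WT window, in 6q12 (chromosome 6, 69000001 to 70000000), had 105495 covered bases and 210849 in H3.1-K27M. The other leading H3.1-WT windows lay in 22q13.33 (from 49000001, 99576 bases), 12q24.33 (from 130000001, 86959), 19q13.42 (from 55000001, 86757) and 20q13.33 (from 59000001, 86407). The H3.1-K27M list covered 130413, 100768, 105991 and 190851 bases there.

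Over all peaks, the H3.1-K27M list had more peaks in dark chromosome bands and fewer in light bands than the H3.1-WT list. Dark Giemsa bands are AT-rich and gene-poor, light bands GC-rich and gene-rich. On autosomes the darkest bands had 17.8 peaks per Mb in H3.1-K27M and 11.9 in H3.1-WT, a ratio of 1.5002. Light bands had 7.65 and 10.3 peaks per Mb, a ratio of 0.743. At a −log10 q of at least 2 the darkest bands no longer held more peaks in H3.1-K27M, with 1677 against 1732, a ratio of 0.968, and the ratio in light bands was 0.482. Over all peaks the dark ratio of peak numbers divided by the light ratio was 2.02 on autosomes and 1.74 on X. It was above 1 on all 18 chromosomes whose darkest bands held peaks in both lists, from 1.32 on chromosome 21 to 2.86 on chromosome 2. Among strong autosomal peaks the quotient was 1.32, with a 95% interval of 0.977 to 1.78 that includes 1, from 78 and 208 peaks in the darkest bands and 307 and 1084 in light bands. By length, strong autosomal peaks covered 1.07 against 1.89 kb per Mb in the darkest bands and 1.01 against 2.80 in light bands. At minimums of 2 and 3 the quotient of peak ratios was 2.01 and 1.52 on autosomes, and 2.07 and 2.45 on X. Among strong peaks on X it was 0.75, the other direction, from 3 and 9 peaks in the darkest bands and 20 and 45 in light bands.

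**Figure D4:**
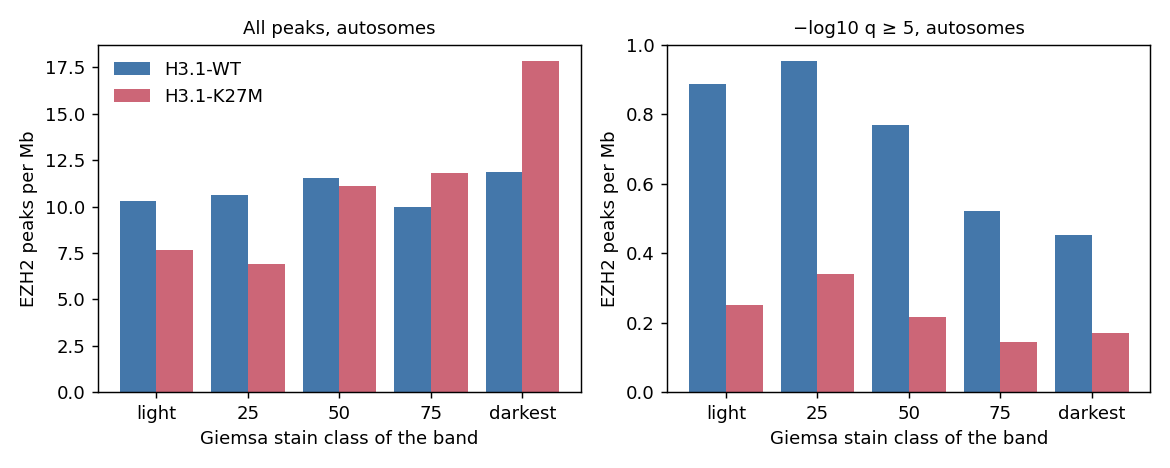
EZH2 peaks per Mb of autosomal bands by Giemsa stain class, for all peaks (left) and for peaks with a −log10 q of at least 5 (right). Over all peaks H3.1-K27M is lower in light bands (7.65 against 10.3) and higher in the darkest bands (17.8 against 11.9), and over strong peaks it is lower in each class.

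The HOX clusters, sets of body-axis homeobox genes and textbook Polycomb targets, were examined through the 4 bands that hold them. Peaks there were fewer in H3.1-K27M. The bands held 89 peaks in H3.1-K27M and 203 in H3.1-WT, a ratio of 0.438. The ratio was 0.976 over all autosomes, and its median was 0.715 over 10000 random sets of autosomal bands matched on stain and length. The HOXA band 7p15.2 had 4 and 23 peaks, the HOXD band 2q31.1 36 and 96, the HOXC band 12q13.13 26 and 42, and the HOXB band 17q21.32 23 and 42. In H3.1-WT, peaks covered 13.2 kb per Mb of the 4 bands, close to 12.03 in autosomal light bands and 12.9 in the darkest. Of the 23 H3.1-WT peaks in the HOXA band, 10 had a −log10 q of at least 2, 4 of at least 3 and 0 of at least 5. The lower number in the HOXA band therefore concerns mostly weak calls. The bands together held 29 and 94 peaks at a −log10 q of at least 2, 3 and 45 at 3, and 2 and 16 at 5. The ratios at these minimums were 0.309, 0.0667 and 0.125, against medians of 0.459, 0.333 and 0.273 over the random sets.

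Of the random sets, 8.44% had a ratio as low over all peaks. At minimum −log10 q values of 2, 3 and 5 this share was 14.6%, 0.96% and 18.7%. The sets were not matched on the number of H3.1-WT peaks, the denominator of the ratio. Over all peaks, 84.4% of them held no more H3.1-WT peaks than the HOX bands. At minimums of 2, 3 and 5 it was 84.0%, 83.9% and 76.0%, so the HOX bands were not typical of the sets in this respect. Single bands differed in rank: among 743 autosomal bands ordered by the ratio of covered length, the HOXA band lay at percentile 5.38 and the HOXD band at 17.0, while the HOXC and HOXB bands lay at 38.9 and 41.2. Among bands of their own stain the percentiles were 3.604, 20.1, 46.5 and 57.1 for HOXA, HOXD, HOXC and HOXB. The bands are 2.5 to 8.3 Mb long and hold many other genes, and peaks in them were not assigned to the clusters. The counts and ranks therefore describe the bands and do not measure EZH2 at the HOX genes.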

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

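The thresholds other than 5 and the autosomes-only values were chosen after seeing the data. The ratio of peak numbers, 1.13 over all peaks, reversed to 0.310 at a −log10 q of at least 5, 0.945 with the fold minimum, 0.958 with peaks within 5000 bases joined, 0.976 on autosomes only, and 0.658, 0.402 and 0.195 at −log10 q minimums of 2, 3 and 10. The ratio of covered length, 1.21, reversed to 0.439 at a minimum of 5 and to 0.789, 0.531 and 0.271 at 2, 3 and 10. It kept its direction under the other alternatives run, from 1.04 on autosomes only to 1.42 with peaks joined. The autosomes-only values show that X sets the direction of the peak number over all peaks. The cause of the other reversals, seen with X included, was not tested.

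Where run, the alternatives below moved the shares of peaks and regions by more than their 95% Wilson intervals, and leaving out Y did not. The Jaccard index has no counting interval. The values below are the share of H3.1-WT peaks overlapped, the share of H3.1-K27M peaks overlapped, the Jaccard index, and the shares of regions in H3.1-WT alone and H3.1-K27M alone. At a −log10 q of at least 5 they were 25.3%, 81.3%, 30.3%, 70.7% and 5.49%. With the fold minimum they were 30.6%, 32.4%, 19.3%, 42.6% and 39.2%. With equal list lengths they were 34.1%, 34.2%, 20.7%, 40.0% and 39.9%. With peaks joined they were 38.02%, 38.6%, 18.9%, 39.4% and 37.4%. A reciprocal overlap of 50% lowered the first pair to 14.5% and 12.9%. On autosomes only the first 3 were 34.7%, 35.3% and 19.4%. The cause was not tested, except that a minimum of 5 leaves fewer H3.1-K27M peaks to overlap.

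The share of covered length on X was 3.16 times as high in H3.1-K27M over all peaks, 3.38 times with equal list lengths and 1.51 times at a −log10 q of at least 5. Alternatives for promoters, annotation classes and gene lists were not run, for want of an hg19 annotation here. No paired analysis was possible because each group has 1 library. Unknown depth limits every comparison of peak number and strength.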

Other observations

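All tests in this part were chosen after the results they bear on had been seen. With 1 EZH2 library per genotype, an effect of the genotype could not be separated from one of the library.

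Both lists placed peaks on chromosome Y of hg19, 74 in H3.1-WT and 61 in H3.1-K27M. Whether the reads behind these calls came from a Y chromosome was not tested, so they are not read as EZH2 on Y. Of the Y peaks 51 and 39 lay in Yp11.32, the band that holds a region shared with X, and 12 and 5 were strong. The other list overlapped 42 and 41 of the Y peaks, 56.8% and 67.2%. Calls that are not read as EZH2 were thus shared between the lists as well.

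Fewer strong EZH2 peaks were called in H3.1-K27M. Loss of the strongest sites from the H3.1-K27M list is argued against. Of the H3.1-WT peaks with a −log10 q of at least 10, 98.2% were overlapped by an H3.1-K27M peak of any strength. This concerns the presence of a call only. An overlap of 1 base does not measure bound EZH2, and without a filter for repeats shared calls need not mean shared binding. Loss of EZH2 at these sites is therefore not decided. Loss from the list stays open for H3.1-WT peaks from 5 to 10, of which 75.6% were overlapped and 335 of 1372 were not. Weaker enrichment or lower depth of the H3.1-K27M EZH2 library may account for the pattern, as may a lower occupancy of EZH2 in H3.1-K27M cells. Neither was tested, because depth is unknown and each genotype has 1 library.

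More EZH2 peaks were called on X in H3.1-K27M. The mix of light and dark bands on X is argued against as the whole cause, because the ratio on X was at least 2.63 times the autosomal ratio in each of the 5 stain classes. A few regions of X are argued against as well, since 27 of 31 windows had over 2 times as many peaks. More copies of X in the H3.1-K27M cells could raise calls along its length. The HRP control of the same genotype would carry such copies too, and how far that offsets them is unknown. The ratio on X over that on autosomes was 3.38 at a minimum −log10 q of 2 and 2.67 at 3. Among strong peaks it was 1.38, with a 95% interval of 0.862 to 2.17. Along X the ratio of peak numbers was uneven: 2.56 on Xp, 4.36 on Xq and 1.03 at 0 to 5 Mb. A difference in copies of X stays open, since read numbers on X in the EZH2 and HRP libraries were not analysed here. A real gain of EZH2 on X is untested.

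The ratio of H3.1-K27M to H3.1-WT peaks was higher in dark than in light bands. Chromosomes 5, 6 and X are argued against as the source, because the dark over light quotient was 2.08 without them. Calls with a −log10 q under 2 are argued against as the whole cause of the quotient, which was 2.01 among the others. By peak number they hold the whole autosomal surplus of H3.1-K27M in the darkest bands, where the ratio was 0.968 at a minimum of 2. By covered length they do not: at that minimum H3.1-K27M still had 7.70 kb per Mb there, against 6.04 in H3.1-WT. Background reads of a library with weaker enrichment may contribute: on autosomes the quotient fell to 1.52 at a minimum of 3 and 1.32 among strong peaks. No such quotient was taken by covered length, so the size of this fall rests on peak number. On X there was no fall up to a minimum of 3, where the quotient was 2.45. Among strong peaks on X it was 0.75, from few peaks. A spread of EZH2 into dark bands at low density could give the autosomal fall too, so these cannot be told apart with 1 library per genotype.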
